A study of Homo sapiens with 4 samples.

How the data were processed

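Total RNA of HEK293 cells was measured on 4 single-colour Illumina Human-6 bead arrays, 24 h after transfection. Samples were grouped by their titles into MIF siRNA (2 arrays, 1# and 2#), control RNA (1 array) and untreated cells (1 array). The design text gives MIF siRNA at 50 and 100 pmol/ml. Only the label of 2# gives a dose, 50 pmol/ml, so no array was assigned the higher one.

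The deposited sample tables hold 1 linear intensity per probe, and per the submitters' processing notes the tool was BeadStudio, with no version given in the sources used here. These intensities had a smallest value of 39.8 and were never negative, and their medians differed between arrays (71.9 to 78.5), so neither background subtraction nor normalization between arrays was apparent in them. No detection p-values were used here. Background left in the signal makes fold changes of dim genes too small. The series value table, also deposited by the authors, holds linear intensities of the same arrays after a normalization between arrays whose method is not given in the sources used here. Each of its columns had a median of 73.8. Its 48702 rows include 1 without values, and from row 19832 on its probe identifiers stand 1 row off those of the sample tables, although the values follow the same order. Its rows were therefore matched by position and named by the sample tables, and the table served as an alternative source. It held 0 columns of other samples.

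Probe genes came from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCh38.p14. Of the 48701 probes, 23687 had 1 gene, 35 had several and 24979 were not listed and stayed unnamed. Of those with 1 gene, 23651 had an identifier in the reference. No genome build is given in the sources used here for the probes, so no coordinates are printed, and the siRNA sequence was not used here.

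Intensities were quantile-normalized between arrays, values under a floor of 32 were set to 32 (0 values were below it), and log2 was taken. Each gene was represented by its probe with the highest mean signal. Genes whose mean signal over the 4 arrays exceeded the median of all probes (75.6) were kept, which left 13755 of 18774 genes. MIF siRNA against control RNA, MIF siRNA against untreated and control RNA against untreated were tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on group means of all 4 arrays. That fit has 1 residual degree of freedom, the difference between the MIF siRNA arrays, so the lone control arrays were assumed to vary like that pair. A fit of MIF siRNA against both control arrays had 2 residual degrees of freedom and counted the difference between the control conditions as spread. Because replication was so thin, genes at least 1.5-fold apart in the same direction in all 4 pairs of a MIF siRNA and a control array were also counted, without a test.

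For 21 gene lists, the median log2 difference of the measured members was placed among 10000 random lists of the same size matched on mean signal. In addition, limma's camera was run with a preset correlation of 0.01 and with an estimated one. The estimated version rests on 2 residual degrees of freedom here, so it had little power to call a list. A list was called when the median of MIF siRNA minus control RNA lay outside the middle 95% of random lists. Members were also tested with Benjamini-Hochberg adjustment over the list alone, using the fit of 2 arrays against 2. In that fit 29.7% of all genes had an unadjusted p under 0.05, so such counts alone do not set a list apart.

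The genes named are MIF and, for MIF siRNA against both control arrays, the 10 higher and 10 lower with the largest smallest-pair difference. For control RNA against untreated they are the 10 higher and 10 lower by difference, and for 1# against 2# the 5 higher and 5 lower. Any gene called by limma would also be named, with up to 4 members of each list by their mean difference from control RNA. Placeholder names were passed over, which happened 1 time, among genes lower in control RNA. DDT and EGR1, outside these ranks, were chosen after their values were seen.

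The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were scaling to the same median in place of quantile normalization, the series value table, floors of 16 and 64, no filter and a filter at percentile 75 of all probes. Also run were the mean of all probes of a gene, an intensity trend in the variance, a 2-fold rule, each control array alone and leaving out each MIF siRNA array. Also chosen after seeing the data were the selection of genes on 2#, and camera and other settings for 3 gene lists added then. A normexp background correction with an offset of 50 and the series value table with its own identifiers were chosen after seeing the data.

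The steps were tested on simulated data made from the control means of the 13755 genes and the spread of control RNA minus untreated, with 200 genes changed equally in both MIF siRNA arrays. The fit of 2 arrays against 2 recovered 34% of genes at the smallest simulated change, 98% at 1.5-fold and 100% at 2-fold, and called 5 of 13555 unchanged genes. The fit on group means recovered 10%, 64% and 100% for MIF siRNA against control RNA and called 6 unchanged genes. The 1.5-fold rule recovered 8% of genes changed 1.5-fold and 100% at 2-fold, with 0 unchanged genes. Of 100 unchanged simulated lists, 4 lay outside the middle 95%, as did 20 of 20 lists shifted by 0.25 on the log2 scale. The simulated noise was independent between genes. In the data the SD of the log2 differences was 0.229 between 1# and 2# and 0.134 between the control arrays. These simulated rates may therefore not hold for the data. R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.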

Results

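Gene expression was measured in HEK293 cells, a human embryonic kidney cell line, after RNA interference against MIF, which encodes the cytokine macrophage migration inhibitory factor. Total RNA from 24 h after transfection was hybridised to 4 Illumina Human-6 bead arrays. Of these, 2 held RNA from cells given MIF siRNA, 1 from cells given a control RNA and 1 from untreated cells. The MIF siRNA arrays are called 1# and 2# as in the labels. The series text gives siRNA doses of 50 and 100 pmol/ml, and the label of 2# gives 50 pmol/ml, while that of 1# gives none. The labels do not say whether 1# and 2# were the same siRNA sequence. Each array reported 48701 probes. The median deposited signal was 77.2 for 1#, 78.5 for 2#, 74.5 for control RNA and 71.9 for untreated cells. After quantile normalization and a filter on dim probes, 13755 genes were compared. Nothing in the labels says that the arrays came from separate cultures, so the p-values below measure only the spread between these arrays. Where both MIF siRNA arrays are in a fit, that spread includes the difference between 1# and 2#. Any difference in dose or siRNA sequence between them then counts as error. The SE values and the counts of called genes are therefore not based on known replicates of 1 condition. The number of arrays limits the precision of every value, and the control conditions had 1 array each.

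MIF was the target of the siRNA, and its signal was lower in both MIF siRNA arrays. The array has 1 probe for MIF, ILMN_1716169, and its normalized signal was 22463 in control RNA, 21908 in untreated cells, 11614 in 1# and 17040 in 2#. The MIF signal was therefore 51.7% of control RNA in 1# and 75.9% in 2#, or -0.95 and -0.40 on the log2 scale. Against untreated cells the log2 differences were -0.92 and -0.36. The mean difference from both control arrays was -0.66 ± 0.18 (SE), with an adjusted p of 0.0744 in limma and both MIF siRNA arrays below both control arrays. On group means the difference was -0.68 from control RNA and -0.64 from untreated cells, and MIF was not called in either comparison. DDT, the closest relative of MIF, had signals of 8492 and 9975 in 1# and 2# against 11234 and 10749 in the control arrays. CXCR4, a chemokine receptor that binds MIF, was 2.67-fold and 1.69-fold above control RNA in 1# and 2#. TXNIP, an inhibitor of thioredoxin, was 2.33-fold and 1.44-fold above it, and the protease gene HTRA1 1.35-fold and 1.56-fold. The list of MIF with its receptors and partners had 14 measured members and a median log2 difference from control RNA of 0.01, at percentile 56 of 10000 matched random lists. Of its members, 4 passed against both control arrays when adjusted over the list alone (3 higher, and MIF lower), 0 did so against control RNA, and 0 passed over all genes.

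The comparison of MIF siRNA with both control arrays asked which transcripts were altered in cells with less MIF. IGFBP5, which encodes an insulin-like growth factor binding protein, was the gene furthest above the control arrays, with signals of 2420 in 1# and 649.5 in 2# against 185.1 in control RNA and 221.6 in untreated cells. NPPB, the gene of B-type natriuretic peptide, was the furthest below them, with 97.1 and 299.2 against 937.1 and 926.2. CCN1, a matricellular protein induced by serum and by mechanical tension, was 6.65-fold lower than control RNA in 1# and 2.96-fold lower in 2#. Also below both controls were ASNS, asparagine synthetase (2.54-fold and 2.12-fold below control RNA in 1# and 2#), PSAT1, a serine synthesis enzyme (2.11-fold and 1.99-fold), and SLC7A5, a transporter of large neutral amino acids (5.72-fold and 1.86-fold).

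The remaining genes named by the fixed rule were ranked by the smallest of the 4 differences between a MIF siRNA array and a control array. On the higher side, FAXDC2 was at least 2.29-fold above the controls in every pair, and the zinc finger genes ZNF467, ZNF503 and TSHZ2 at least 2.25-fold, 2.09-fold and 2.09-fold. FXYD6, a regulator of the sodium-potassium pump, was at least 2.25-fold higher and the orphan nuclear receptor gene NR2F1 at least 2.21-fold. PARM1, the steroid-converting aldo-keto reductase gene AKR1C3 and the LIM domain gene CRIP2 followed at 2.13-fold, 2.10-fold and 2.06-fold. On the lower side, ACTBL2 and ELAPOR1 were at least 1.95-fold and 1.94-fold below the controls. TNFRSF12A, the receptor of the cytokine TWEAK, was at least 1.91-fold lower, and its signal of 2683 in control RNA stood 1.47-fold above that in untreated cells. The ribosome assembly factor gene NIP7 was at least 1.88-fold lower and CHORDC1, which encodes a partner of the chaperone HSP90, at least 1.82-fold.

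**Figure D1:**
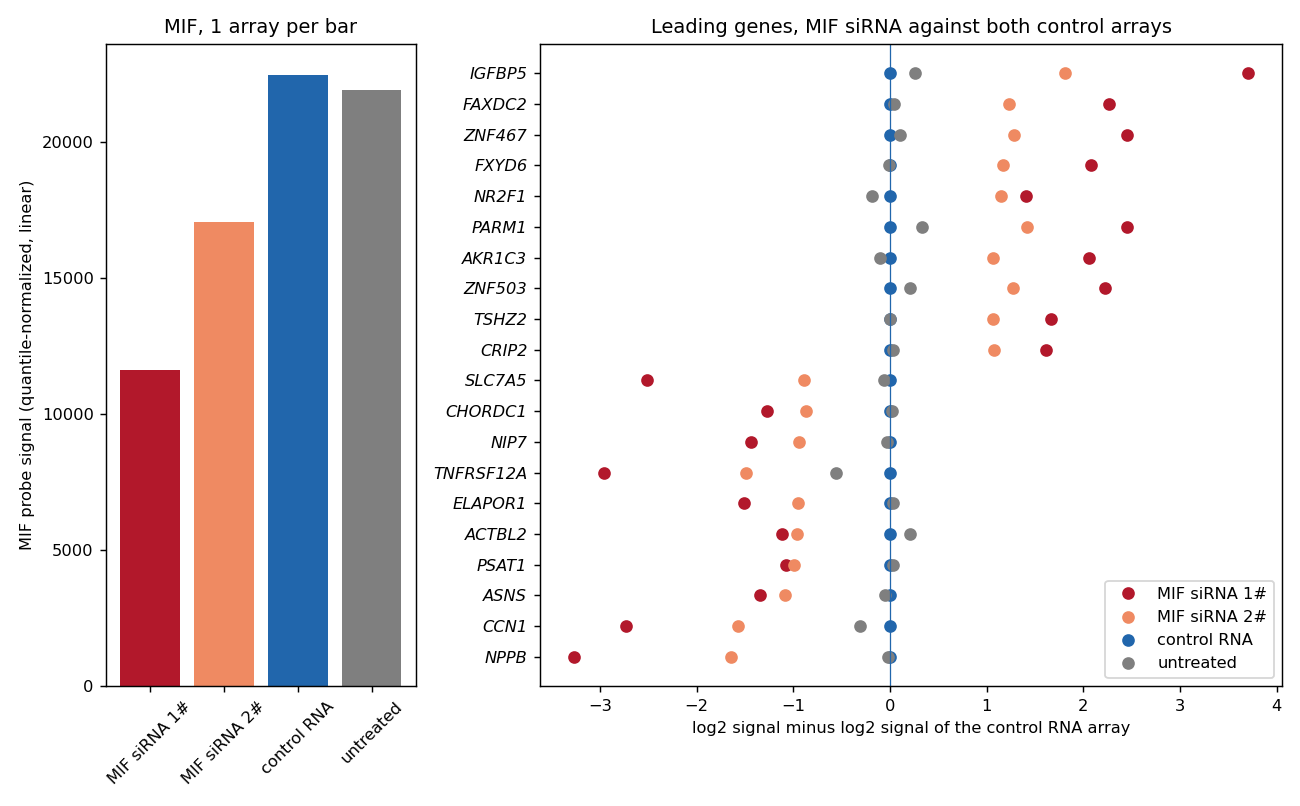
Left, quantile-normalized MIF signal on each of the 4 arrays (linear scale), lower in 1# (11614) and 2# (17040) than in control RNA (22463) and untreated cells (21908). Right, log2 signal of the 20 leading genes relative to the control RNA array, 1 point per array; each gene's point for 1# lies further from control RNA than its point for 2#.

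Both MIF siRNA arrays were at least 1.5-fold from both control arrays in 157 genes, 102 higher and 55 lower (65% higher). The other 2 ways of setting 2 of the arrays against the other 2 gave 0 and 0 genes by this rule. Those splits place 1# and 2# on opposite sides, so genes that follow the MIF siRNA cannot pass in them. The limma fit of 2 arrays against 2 called 0 genes at an adjusted p of 0.05. Its smallest adjusted p was 0.0501, and 4090 genes had an unadjusted p under 0.05, against 23 and 40 in the other splits. NR2F1 had a difference of 1.37 ± 0.12 (SE, log2, adjusted p 0.0501), IGFBP5 2.63 ± 0.55 (adjusted p 0.0544) and NPPB -2.45 ± 0.47 (adjusted p 0.0518). The count of 0 did not hold under other settings: scaling each array to the same median gave 1581 calls (86.3% higher), and by the 1.5-fold rule 262 genes, 90.8% higher. An intensity trend in the variance gave 1007 calls, no filter on dim probes 590 and a stricter filter 927. Without 1# the fit called 1542 genes and without 2# 4624, with the lone MIF siRNA array assumed to vary like the control pair, and the 1.5-fold rule gave 178 and 1243 genes.

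Gene groups fixed beforehand were compared through the median of their members. Genes of the proteasome, the complex that degrades tagged proteins, had a median log2 difference from control RNA of -0.27, with camera adjusted p = 0.622 with an estimated correlation. Of 24 measured members, 19 were below both controls in both MIF siRNA arrays and 0 above them in all 4 pairs. Among all genes, 61.4% moved the same way, up or down, in all 4 pairs. The list's median was -0.26 in 1# and -0.21 in 2# against control RNA, and that of the mean of the arrays lay below all 10000 matched random lists. PSMA6 was 1.77-fold and 1.55-fold below control RNA in 1# and 2#, and PSMD14 1.69-fold and 1.39-fold, whereas control RNA minus untreated gave a median of 0.04. Against untreated cells the list stood at percentiles 0.06 in 1# and 0.05 in 2#. Adjusted over the list alone, 8 members passed against both control arrays, all lower, and 0 against control RNA, while over all genes 0 passed.

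Genes of the unfolded protein and amino acid stress response had a median of -0.17 against control RNA (percentile 0.83), with 13 of 22 members lower in all 4 pairs and 2 higher. Among all genes, 61.4% moved the same way, up or down, in all 4 pairs. Adjusted over the list alone, 7 members passed, 6 of them lower. Beside ASNS and PSAT1, the cystine transporter gene SLC7A11 was 1.64-fold and 1.41-fold below control RNA, and the stress-induced pseudokinase gene TRIB3 1.51-fold and 1.35-fold. The camera test gave adjusted p = 0.622 with an estimated correlation. Heat shock genes had a median of -0.17 (percentile 1.87), led by HSPA1B, an inducible HSP70 gene with 2.41-fold and 1.76-fold lower signals. HSPH1 was 1.98-fold and 1.47-fold lower, and 4 of 15 members passed against both control arrays when adjusted over the list alone, all lower, with 0 passing against control RNA. For this list the camera test gave adjusted p = 0.622 with an estimated correlation. Control RNA was itself below untreated cells in the heat shock list, with a median of -0.09 at percentile 2.07. Against untreated cells the stress response list stood at percentiles 4.9 in 1# and 0 in 2#, and the heat shock list at 4.43 and 2.48. Without 2# the stress response list stood at percentile 4.17 against control RNA, and with each array scaled to the same median the heat shock list stood at 5.52, both inside the middle 95%.

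The immediate-early and ERK feedback genes, which respond within minutes to growth factors, had a median of -0.16 (percentile 0.22), with -0.22 in 1# and -0.10 in 2#, the latter also the value without 1#. Of 22 members, 12 passed when adjusted over the list alone, 8 lower and 4 higher. CCN2 was 3.13-fold and 1.64-fold below control RNA, FOSL1 2.44-fold and 1.45-fold, and IER3 1.77-fold and 1.72-fold, while EGR1 was 0.63 and 0.59 higher on the log2 scale. Against untreated cells the list lay inside the middle 95% in both arrays, with medians of -0.11 in 1# (percentile 3.94) and -0.03 in 2# (percentile 21.4). The camera test gave adjusted p = 0.633 with an estimated correlation, and with each array scaled to the same median the list's median was -0.02 (percentile 5.83). Hypoxia and glycolysis genes had a median of -0.19 (percentile 0.07), with -0.29 in 1# and -0.07 in 2#, and percentiles of 0.03 and 1.4 against untreated cells. The hexokinase gene HK2 was 1.73-fold and 1.15-fold below control RNA and ANKRD37 1.68-fold and 1.51-fold, whereas DDIT4, which is also induced by other stresses, was 2.05-fold and 1.48-fold above it. Only ANKRD37 passed when adjusted over the list alone, and the camera test gave adjusted p = 0.633 with an estimated correlation. Without 1# the hypoxia list stood at percentile 3.98, and with each array scaled to the same median at 4.20, both inside the middle 95%.

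Groups with higher medians included the cyclin D, CDK and CDK inhibitor genes, at 0.22 (percentile 98.3). CDKN1B, which encodes the CDK inhibitor p27, was 2.60-fold and 1.58-fold above control RNA in 1# and 2#, and CDKN1A, which encodes p21, 1.83-fold and 1.28-fold. CCND2 was 1.73-fold and 1.64-fold higher, and the retinoblastoma gene RB1 was 0.86 and 0.32 higher on the log2 scale. Of 16 members, 6 passed when adjusted over the list alone, all higher, and camera gave adjusted p = 0.622 with an estimated correlation. Against untreated cells this list stood at percentiles 96.1 in 1# and 99.1 in 2#, and with the mean of all probes of a gene its median was 0.11 (percentile 87), inside the middle 95%. The p53 targets had a median of 0.18 (percentile 98), with TP53INP1 2.92-fold and 1.90-fold and ZMAT3 1.88-fold and 1.47-fold above control RNA. The proapoptotic gene BAX was 1.64-fold and 1.29-fold below it. Of 22 members, 4 passed when adjusted over the list alone (3 higher, 1 lower), and camera gave adjusted p = 0.789 with an estimated correlation. Against untreated cells the p53 list lay inside the middle 95%, at percentiles 94.7 in 1# and 94.1 in 2#, as it did without 1# (percentile 93) and with the mean of all probes of a gene (96.4). The adhesion, matrix and migration genes had a median of 0.16 (percentile 98.7) against control RNA, but 0.02 and -0.01 for 1# and 2# against untreated cells. In control RNA minus untreated their median was -0.13 (percentile 0.01). SPARC was 1.51-fold and 1.40-fold above control RNA and TGFBI 2.19-fold and 1.39-fold below it, with 0 of 24 members passing when adjusted over the list alone. Camera gave adjusted p = 0.927 with an estimated correlation, and without 1# or without 2# the list stood at percentile 96 or 94.2.

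Interferon-stimulated genes had a median of 0.13 against control RNA (percentile 96.1), inside the middle 95% of random lists. In 1# alone the percentile was 98.6, and against untreated cells it was 99.3 in 1# and 99 in 2#. Of 27 members, 15 were higher in all 4 pairs and 2 lower, while 61.4% of all genes moved the same way, up or down. When adjusted over the list alone, 5 members passed, all higher. IFI44L was 4.40-fold and 1.58-fold above control RNA, IFIT2 2.40-fold and 1.59-fold, IFIT1 1.96-fold and 1.46-fold, and IFIT3 1.69-fold and 1.63-fold. Camera with the preset correlation called this list (adjusted p 0.00685), and gave adjusted p = 0.622 with an estimated correlation. The list's median in control RNA minus untreated was 0.02 (percentile 83.1).

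The other lists lay inside the middle 95% of random lists for the mean of both arrays against control RNA. The G1/S list had a median of 0.14 (percentile 92.9), with the replication licensing gene CDT1 2.53-fold and 1.89-fold above control RNA and CDC25A 1.86-fold and 1.35-fold below. The G2/M list had a median of 0.00 (percentile 43.8), with CDC25B 1.70-fold and 1.43-fold above and UBE2C 1.82-fold and 1.37-fold below. The BCL2 family and caspase list had a median of -0.08 (percentile 7.6), with BMF, a BH3-only proapoptotic gene, 3.88-fold and 2.23-fold above control RNA and the prosurvival gene MCL1 1.66-fold and 1.54-fold below. The NF-kB and inflammatory list stood at -0.01 (percentile 36.2), with the NF-kB inhibitor gene NFKBIA 2.28-fold and 1.59-fold above. The glucocorticoid-induced list stood at 0.15 (percentile 89.7), with TSC22D3 3.20-fold and 1.98-fold above control RNA and KLF9 1.94-fold and 1.45-fold. Against untreated cells it stood at percentile 97.7 in 1#, outside the middle 95%, and 96.6 in 2#, inside it. When adjusted over the list alone, these 5 lists had 2, 7, 1, 1 and 4 passing members in that order.

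Oxidative stress genes had a median of -0.12 (percentile 5.18), with HMOX1 1.55-fold above control RNA in 1# and 1.56-fold in 2#, and SRXN1 1.81-fold and 1.17-fold below. Cholesterol and fatty acid synthesis genes had a median of -0.05 (percentile 16.6), with percentiles of 0.85 and 0.87 for 1# and 2# against untreated cells and 2.89 for control RNA. Here HMGCS1 was 2.08-fold and 1.57-fold below control RNA and MSMO1 2.00-fold and 1.65-fold, whereas the desaturase gene FADS1 was 2.01-fold and 1.38-fold above. The mitochondrial respiratory chain genes had a median of -0.08 (percentile 10.4), with UQCRB 2.05-fold and 1.32-fold and UQCRC2 1.73-fold and 1.42-fold below control RNA. RNA interference genes had a median of 0.20 (percentile 95.6), with AGO2, the slicing Argonaute, 1.47-fold and 1.44-fold above control RNA. These 4 lists had 3, 8, 4 and 6 members passing when adjusted over the list alone. The housekeeping list had a median of 0.04 (percentile 66.7) and 0 such members. The list of markers of other cell types held genes of fibroblasts, blood, endothelium and hepatocytes and a few epithelial genes. Its median was 0.00 (percentile 44.4), with COL3A1 2.45-fold and 1.27-fold above control RNA and 1 member, the epithelial gene MUC1, passing. When each array was scaled to the same median, the medians of the BCL2 family and caspase, NF-kB, cholesterol and other-cell-type lists changed sign.

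In all, 8 of the 21 lists lay outside the middle 95% of random lists, 3 above and 5 below. Over the 21 lists, 0 members passed over all genes. When adjusted over the list alone, 88 passed against both control arrays, the comparison behind every such count here unless control RNA is named. Against control RNA 9 passed, 4 of them immediate-early, 2 stress response, 2 G1/S and 1 cyclin D, CDK and CDK inhibitor genes, and 0 in the other lists. In the fit against both control arrays, 29.7% of all 13755 genes had an unadjusted p under 0.05. Passing members alone therefore do not set a list apart, and the G2/M list, at percentile 43.8, had 7. Camera with a preset correlation of 0.01 called 7 lists and with an estimated correlation 0. The estimated version rests on 2 residual degrees of freedom, and its p was also larger in lists whose estimate lay below 0.01. Its lack of calls is therefore no evidence against a coordinated change. The proteasome list was the only one of the 8 that stayed outside the middle 95% under every other scaling, source, filter, probe rule and left-out array. Both floors left the median of every list unchanged, so they did not test this. The percentiles describe these arrays and are not p-values over samples, and both MIF siRNA differences carry the chance values of the same control RNA array.

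**Figure D2:**
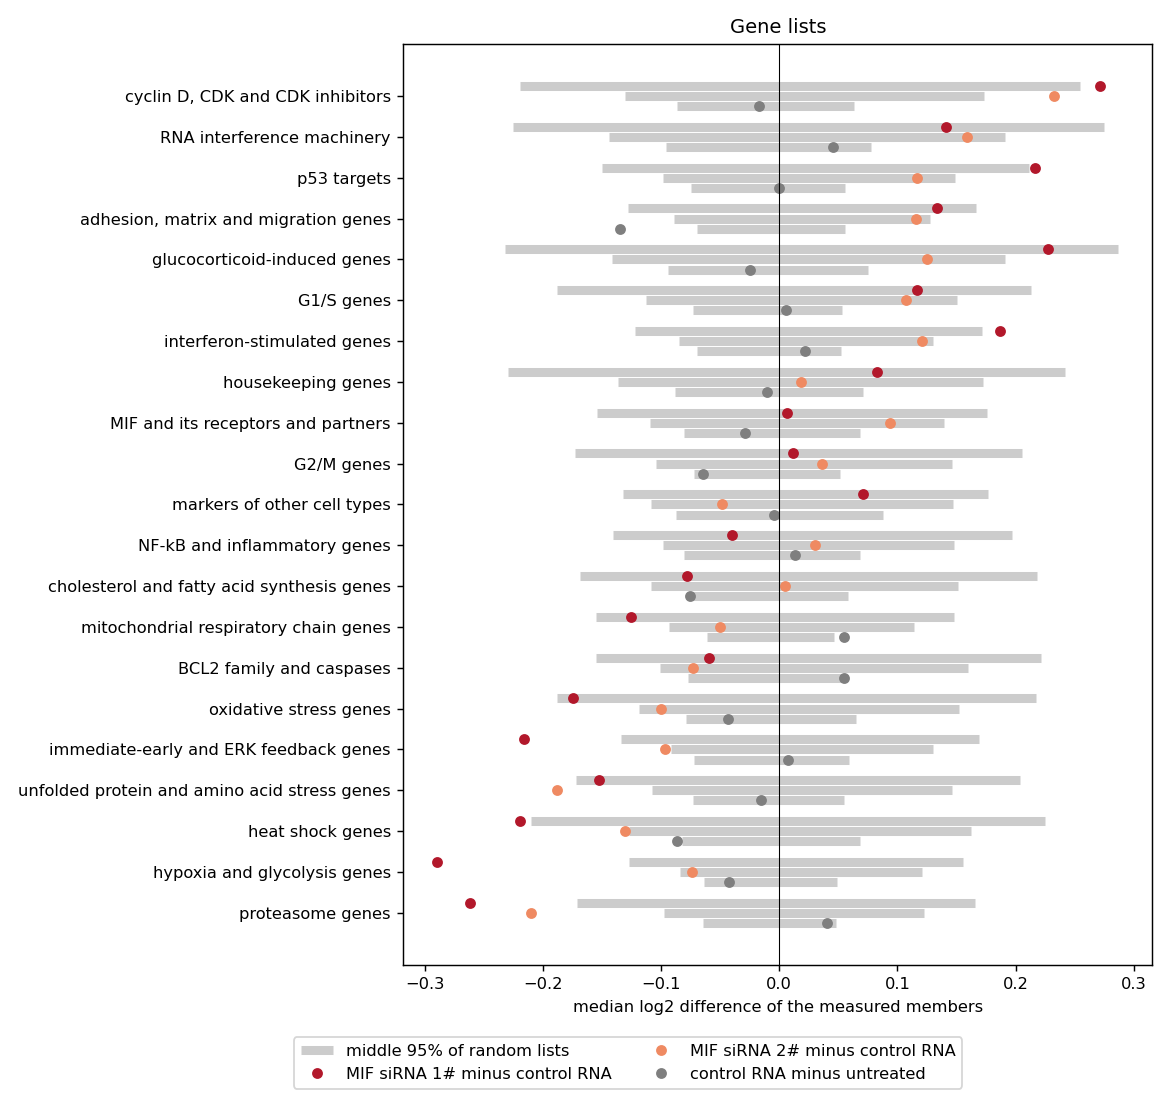
Median log2 difference of the measured members of each fixed gene list (x axis) for 1# minus control RNA, 2# minus control RNA and control RNA minus untreated, with grey bars for the middle 95% of 10000 matched random lists. The proteasome medians in 1# (-0.26) and 2# (-0.21) lie left of their bars, while the control RNA median (0.04) lies inside its bar.

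The comparison with control RNA alone set MIF siRNA against another introduced RNA. Here IGFBP5 was 13.1-fold above control RNA in 1# and 3.51-fold in 2#, and PARM1 5.49-fold and 2.68-fold. NPPB was 9.65-fold and 3.13-fold below it and TNFRSF12A 7.78-fold and 2.80-fold. The mean differences were 2.76 ± 0.73 for IGFBP5, 1.94 ± 0.41 for PARM1, -2.46 ± 0.62 for NPPB and -2.22 ± 0.57 for TNFRSF12A (SE, log2). Against untreated cells the mean differences were 1.61 for PARM1, -2.44 for NPPB and -1.67 for TNFRSF12A, and IGFBP5 was 3.45 higher in 1# and 1.55 higher in 2#. With limma on 3 group means and 1 residual degree of freedom, 0 genes were called against control RNA, with a smallest adjusted p of 0.252 and 2308 genes at an unadjusted p under 0.05. Against untreated cells 0 genes were called, with a smallest adjusted p of 0.38 and 1764 genes at an unadjusted p under 0.05. With an intensity trend in the variance, limma called 76 and 22 genes in these comparisons.

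Control RNA and untreated cells differed by at least 1.5-fold in 13 genes, 9 higher and 4 lower in control RNA, and by 2-fold in 0. FKBP2, a peptidyl-prolyl isomerase gene of the secretory pathway, was 1.74-fold above untreated cells, with a signal of 696.4 against 399.9. MYDGF was 1.67-fold higher, GAR1, a component of H/ACA small nucleolar ribonucleoproteins, 1.64-fold, and the uracil-DNA glycosylase gene UNG 1.62-fold. RAC3, ENSA, FOXJ3, HNRNPA3, ZFYVE21 and DDAH2 followed, between 1.58-fold and 1.49-fold higher. The lowest in control RNA were the 28S ribosomal RNA gene RNA28SN5 (1.54-fold lower), SNORA25 (1.53-fold) and IGFBP4 (1.51-fold). PRRC2C, LUC7L3, THBS1, ANKRD50, ASCC3, TMEM86B and ATP1B1 were between 1.46-fold and 1.39-fold lower. THBS1, encoding thrombospondin 1, had its highest signal in untreated cells (524.1, against 364.3 in control RNA, 299.7 in 2# and 185 in 1#). With the spread taken from the MIF siRNA pair, limma called 0 genes, the smallest adjusted p was 1 and 65 genes had an unadjusted p under 0.05. Across genes the SD of the log2 differences was 0.134, against 0.397 for 1# and 0.248 for 2# minus control RNA.

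The 2 MIF siRNA arrays differed from each other by at least 1.5-fold in 295 genes, 167 higher and 128 lower in 1#, with an SD of the log2 differences of 0.229. With each array scaled to the same median the count was 343, 259 higher and 84 lower (75.5% higher). IGFBP5 was 3.73-fold higher in 1# than in 2#. The replication-dependent histone genes H2BC5 and H1-2 were 3.11-fold and 2.82-fold higher in 1#, and both were within 1.13-fold of control RNA in 2#. IFI44L was 2.77-fold higher in 1#, and CGA, the alpha subunit of glycoprotein hormones, 2.71-fold. TAGLN, which encodes the actin-binding protein transgelin, was 3.45-fold lower in 1#, NPPB and SLC7A5 each 3.08-fold lower, TNFRSF12A 2.78-fold lower and the oxidised LDL receptor gene OLR1 2.44-fold lower. With 1 array each, these differences have no replicate check. The count at 2-fold was 32.

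Each MIF siRNA array was also set against a different control array, so that no array was shared. Of 1448 genes at least 1.5-fold apart between 1# and untreated cells, 1417 (97.9%) differed in the same direction between 2# and control RNA. The median ratio of the log2 difference of 2# to that of 1# was 0.52 in these genes, which were selected on 1#, a choice that favours smaller differences in 2#. With the control arrays exchanged, 1728 of 1789 genes (96.6%) had the same direction and the median ratio was 0.41. Across 13755 genes, which are not independent replicates, Pearson's r of the differences was 0.749 and 0.715 for these pairings. Among 1243 genes with 1# at least 1.5-fold from both control arrays, 2# lay between 1# and both controls in 1219 (98.1%). With genes selected on 2# instead, which favours 2#, 1# lay further out than 2# in 150 of 178 (84.3%). The median ratio of 1# to 2# was then 1.17 over 397 genes and, with the control arrays exchanged, 1.41 over 248.

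**Figure D3:**
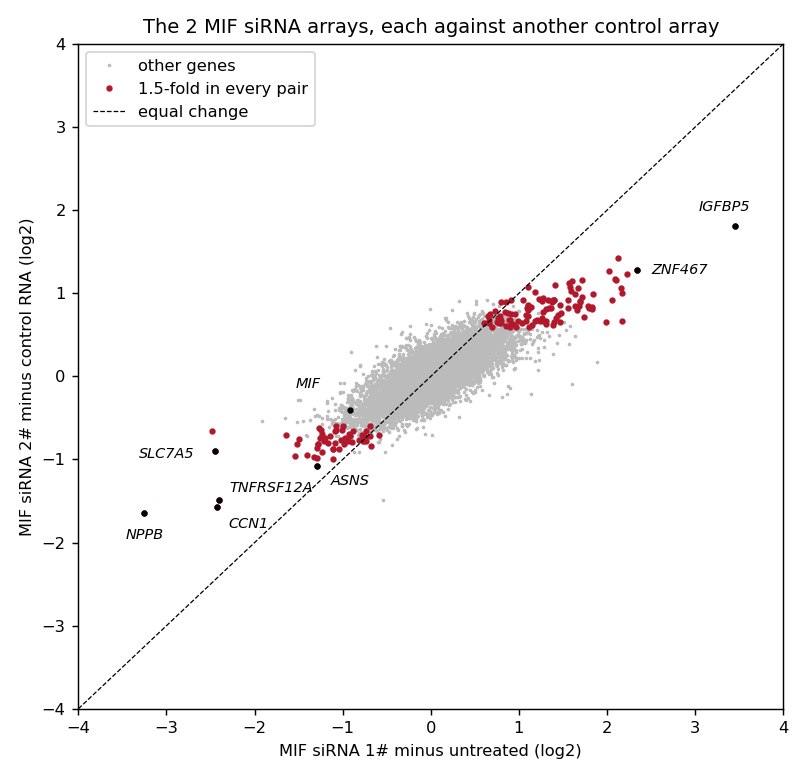
Log2 difference of 1# from untreated cells (x axis) against that of 2# from control RNA (y axis), 1 point per gene for 13755 genes, with the 157 genes at least 1.5-fold from both controls in red, named genes in black and the line of equal change dashed. The median ratio of 2# to 1# was 0.52 among the 1448 genes selected as at least 1.5-fold apart on the x axis, and that of 1# to 2# was 1.17 among the 397 selected on the y axis.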

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

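The tests of a mixture, of a lower dose, of background and of both kinds of signal limit, and the selection of genes on 2#, were chosen after the results they measure were seen.

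Probes without a single gene name were outside the comparisons of the report. Of 8213 such probes above the dim filter, 22 were at least 1.5-fold from both control arrays in both MIF siRNA arrays, 7 higher and 15 lower. Between single arrays, 323 such probes were 1.5-fold apart for 1# and control RNA and 73 for 2# and control RNA. For control RNA and untreated cells the count was 7. ILMN_1764709 had signals of 1486.1 in 1# and 1112.3 in 2# against 443.5 in control RNA and 491.7 in untreated cells, and ILMN_1685240 had 348.6 and 719.9 against 1394.1 and 1238.4.

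Array 2# lay between 1# and both control arrays in 98.1% of the 1243 genes in which 1# was at least 1.5-fold from both, a selection that favours this order, and in 84.3% of the 178 genes selected on 2#, which works against it. A shared control array is argued against as the source, since the smaller correlation across genes with different control arrays was 0.715. Partial dilution of responding cells or RNA in 2# would give genes higher and genes lower in 1# equal linear shares. Their median shares differed by -0.16 (95% interval -0.19 to -0.127), beyond the limit of 0.1 set for this test. The interval came from resampling genes and does not measure the spread between arrays. In addition, 3 further calculations added after that value was seen gave -0.08, -0.18 and 0.09 by control pairing and scaling. A mixture therefore cannot be told apart from a weaker response. A lower dose in 2# may also account for the order. The test set for it asked only that MIF in 2# lie between 1# and the control arrays, and the log2 decrease of MIF in 2# was 0.419 of that in 1#. A mixture or another siRNA sequence could give such a share too, so it does not favour dose. A lower dose stays open because each siRNA array stands alone and the label of 1# gives no dose. The labels also do not say whether both held the same siRNA sequence.

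The decrease of MIF in 1# was exceeded by 157 genes in that array and in 2# by 599. Background left in the signal is argued against, since subtracting the median of all probes from every signal enlarged the MIF log2 difference by 0.00305, and so is an upper limit of the scale at the MIF signal, since the highest signal, 40131.2, was 1.72 times the highest of MIF. Of 133 genes nearly as bright as MIF in the control arrays (at least 2/3 of its signal), 2 were lower than MIF was in 1#, HSPA1B at -1.27 and BCYRN1 at -1.18, the latter named after its values were seen. For a gradual compression of bright signals below the upper limit, 0 was set as the prediction and 3 as evidence against it. The count lies between them. With 157 of all 13755 genes falling further than MIF in 1#, few of 133 would do so without compression either. Such compression therefore cannot be told apart from a partial knockdown. A knockdown of that size stays among the open explanations as a biological one.

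The series value table and the sample tables name 28870 of their probes differently. If the table's names were 1 row off, abundant ribosomal protein probes would look dim under them. Of 40 such probes, 67.5% had a signal over 1000 under the names of the sample tables and 10% under those of the series value table, a difference of 57.5 percentage points, consistent with a shift of the names by 1 row. No biological explanation was tested.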

How the results depend on the processing

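The normexp correction and the series value table with its own probe names were chosen after seeing the data. Of the table's own names, 28870 differ from those of the sample tables, and the ribosomal protein probes above argue that they are shifted. Many genes then carry the values of other probes in that setting, so its changes do not measure how stable the results are. MIF was lower in every setting run, from -0.95 (without 2#) to -0.40 (without 1#) against control RNA and from -0.92 to -0.36 against untreated cells. No result changed direction past its threshold. For MIF siRNA against both control arrays, where limma called 0 genes with a smallest adjusted p of 0.0501, the count was 1581 with each array scaled to the same median, 590 without the dim filter, 927 with a stricter filter, 1007 with an intensity trend and 531 with the series value table under its own names. It was 1542 to 4624 with 1 MIF siRNA array left out, and 0 with the series value table by position, the mean of all probes, normexp and both floors. The intensity trend gave 76 calls against control RNA and 22 against untreated cells. The 157 genes at 1.5-fold in every pair became 262 with scaling to the same median, 13 at 2-fold, 361 against control RNA alone and 178 to 1243 with 1 array left out. The 295 genes between 1# and 2# became 32 at 2-fold. With scaling to the same median, the median difference of all genes from control RNA was 0.0953 in 1# and 0.0642 in 2#, against 0.00711 and 0.0153 with quantile normalization. Under it 2 lists moved outside the middle 95%, interferon (0.25) and mitochondrial (-0.20), and 4 moved inside, immediate-early (-0.0165), hypoxia (-0.0725), heat shock (-0.19) and adhesion (0.21). By position in the series value table the heat shock list moved inside (-0.14). Without the dim filter the interferon list moved outside (0.13) and heat shock inside (-0.14). With the stricter filter the BCL2 family moved outside (-0.14), and the stress response (-0.14) and adhesion (0.16) lists inside. With the mean of all probes the interferon list moved outside (0.13), and p53 (0.14), cyclin D (0.11), stress response (-0.14), heat shock (-0.18) and adhesion (0.12) inside. Under the series table's own names p53 (0.0116), cyclin D (0.0661), hypoxia (-0.0194), stress response (-0.10) and heat shock (-0.0217) moved inside and RNA interference (0.25) outside. Camera with the preset correlation gave adjusted p 0.149 for p53, 0.11 for immediate-early and 0.789 for adhesion, all 3 not called, and 0.00685 for interferon and 0.0147 for mitochondrial genes. With an estimated correlation the adjusted p was 0.789 for p53, 0.622 for cyclin D, stress response, heat shock and proteasome, 0.633 for immediate-early and hypoxia, and 0.927 for adhesion. With 1 MIF siRNA array left out, medians ran from 0.12 to 0.22 for p53, 0.12 to 0.19 for interferon, -0.29 to -0.0738 for hypoxia, -0.22 to -0.0969 for immediate-early genes, -0.19 to -0.15 for the stress response and 0.12 to 0.13 for adhesion. Apart from the shifted names of the series value table, the cause of these differences was not tested. No list moved with normexp or with either floor, and both floors left every list median as it was. Leaving out a MIF siRNA array left no residual degree of freedom for the fits on group means and nothing to compare between 1# and 2#, so no value is given there. No paired analysis was possible because the control conditions had 1 array each and the labels pair no arrays. No signal was under 39.8, so background was left in the values, which compresses the differences of dim genes.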

Other observations

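The gene lists of this part were written after the leading genes were seen, with those leading genes left out of them, and camera and the other settings were run on them after their medians were seen.

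NIP7, a ribosome assembly factor, was among the leading lower genes, and other genes that build ribosomes were lower with it. MRTO4, a factor in the assembly of the large ribosomal subunit, had signals of 1407.2 in 1# and 2078.9 in 2# against 3404.3 in control RNA and 2961.9 in untreated cells. WDR12, a partner of BOP1 and PES1 in ribosomal RNA processing, had 1682.3 and 2187.2 against 3182.1 and 3328.3, and RRS1, which brings 5S RNA to the large subunit, 919.6 and 956.3 against 1504.9 and 1530.9. LYAR, PES1 and RRP12 had log2 differences from control RNA of -0.84, -0.72 and -0.87 in 1# and -0.48, -0.41 and -0.33 in 2#. Of 31 measured ribosome biogenesis factors, 26 were lower in all 4 pairs of a MIF siRNA and a control array and 0 higher. Among all genes, 61.4% moved the same way, up or down, in all 4 pairs. The median of the factors was -0.47 in 1# and -0.27 in 2# against control RNA, at percentile 0 of 10000 matched random lists in both arrays, while control RNA minus untreated stood at percentile 40.6. The list stayed at percentile 0 in both arrays against control RNA with each array scaled to the same median (-0.41 and -0.24), the series value table, no filter, a stricter filter, the mean of all probes and normexp. Camera gave p = 1e-10 with the preset correlation and p = 0.193 with an estimated correlation of 0.455, so the call depends on the version of the test. Correlation between members need not be the reason. In the stress response list, with an estimated correlation of -0.0229, camera p also rose, from 0.000404 to 0.0601. Over all genes 0 of them passed. As a hypothesis only, a coordinated decrease of ribosome biogenesis factors may accompany MIF siRNA, and whether it follows MIF itself was not tested, since no array restores MIF.

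CCN1, CCN2 and TAGLN, all targets of the serum response factor or of YAP, were among the lower genes, which led to a test of other such targets. Against control RNA their median was -0.19 in 1# (percentile 0.22) and -0.03 in 2# (percentile 18.9). The list thus lay outside the middle 95% in 1# and inside it in 2#. A coordinated decrease, set to require both arrays, was not met, and the difference between 1# and 2# was not tested. The median of the mean of both arrays, -0.13, lay outside the middle 95% (percentile 0.58), and camera gave p = 0.0506 with the preset correlation and p = 0.544 with an estimated correlation. TPM1 stood at -1.14 in 1# and -0.58 in 2#, whereas ACTA2 stood at 0.97 and 0.62. TXNIP, BMF and TSC22D3, which FOXO factors induce, were among the higher genes. Against control RNA, other FOXO targets lay inside the middle 95% of random lists, with medians of 0.19 in 1# (percentile 96.4) and 0.10 in 2# (percentile 89.2). Against untreated cells they lay outside it in 1# (0.27, percentile 99.7) and inside it in 2# (percentile 92.3). Camera gave p = 0.0892 with the preset correlation and p = 0.351 with an estimated correlation, and 5 of the 20 were also in the fixed lists. BCL6 stood at 1.48 in 1# and 0.74 in 2# and CITED2 at -0.68 and -0.49.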
